A study of Homo sapiens with 52 samples.

How the data were processed

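RNA from the nucleated cells of peripheral blood of 21 controls and 31 patients with a first myocardial infarction was measured, per the labels, on 1 oligonucleotide array per donor. The labels' protocols name 100 ng of total RNA, column purification and biotin-labelled cRNA. The deposited table holds log2 expression values of 54675 probe sets on 52 arrays, made by the authors with RMA, per the submitters' processing notes, with no version given. The table's values run from 2.13 to 15.41, so no gene had been centred. Array medians run from 5.33 to 5.50 and array interquartile ranges from 2.63 to 3.11, so the arrays do not share one distribution, and whether all were quantile-normalized together is not known. The background correction and normalization inside RMA are not given in the sources used here, nor are scan dates or batches. An expression value on this scale is a brightness, so a probe set near the lower end says little about its transcript, and differences there are compressed.

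Groups were taken from the labels, as control (21), infarction without recurrence (26) and infarction with recurrence (5). Replicate numbers follow the order of the samples and pair nothing. No pair of arrays held the same values, the highest correlation between any 2 being 0.993. Probe sets were named through the platform's gene table, in which 41091 of 54613 non-control probe sets name 1 gene, 1801 name several and 11721 are not listed. Of the 41091, 41037 took their current symbol through the Entrez identifier from a RefSeq table of assembly GRCh38.p14, and 54 kept the platform's name. No coordinates are given, because the files name no build. Left out were 62 control probe sets, probe sets with several genes or none, and genes whose level could reveal a donor's sex.

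The design was fixed before the data were examined. Probe sets with a mean over all arrays below the 40th percentile of the non-control probe sets (4.87 log2) were removed, and the brightest remaining probe set stood for each gene, which left 14319 genes. Linear models were fitted to the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The comparisons were all patients against controls, patients with against those without recurrence (31 arrays), and each patient group against controls in a fit of all 3 groups. A difference is the mean of the first group minus that of the second, and SE is the standard error of that fit. Gene lists (31, for blood cell types, inflammation, lipid handling, metabolism and cardiac muscle) were tested with limma's camera at a preset correlation of 0.01, over lists with at least 5 tested members, and again with an estimated correlation and with fry. List means per array were compared with a permutation test, with 100000 permutations for patients against controls and all 169911 splits for recurrence. Tests were run on simulated values of 14319 genes with the genes' own means and spreads, and with errors drawn independently for each gene. For patients against controls they recovered 90% of genes changed by 0.5 log2 and 100% of those changed by 1 log2. For recurrence against no recurrence they recovered 61% and 91%. Of the simulated genes called, 8.2% were false for patients against controls and 3.8% for recurrence. In each simulation 100 genes were changed by each size. Genes on the real arrays move together, unlike the simulated ones, so these rates may be too high for the real data.

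The text names the 10 largest rises and the 10 largest falls among called genes, or, where fewer than 5 genes were called, the 5 genes with higher and the 5 with lower values that had the smallest unadjusted p, and up to 4 members of each list described, those with the smallest unadjusted p. The same genes are named in the comparisons of each patient group with controls. Names outside this rule are said to have been chosen after their values were seen. Genes read by a probe set ending in _x_at are called possibly cross-hybridising.

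The alternatives were no filter or a filter at the 60th percentile, the mean of a gene's probe sets, each probe set by itself, no probe sets ending in _x_at or _s_at, quantile normalization of the deposited values, centring on the array median, array weights, a trended and robust prior, the means of the neutrophil, T cell and erythroid lists as covariates, other thresholds with a change of at least 1.2-fold, another fit of the groups, and leaving out each array in turn. Chosen after seeing the data were the array interquartile range as a covariate, leaving out the 5 arrays with the lowest mean correlation with the others, the means of the cytotoxic and platelet lists as covariates, and the permutation test of list means. A gene followed a list where its correlation with the list's mean across arrays, after removing group means, was at least 0.5. Figures were drawn with matplotlib 3.10.9.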

Results

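Gene expression was measured on oligonucleotide microarrays in the nucleated cells of peripheral blood from people with a first myocardial infarction and from controls whose echocardiogram was normal. The 52 arrays held 21 controls and 31 patients, sampled within 48 hours of the infarction. Among the patients, 26 had no later recurrent event and 5 had one. Each array was treated as a separate donor, as the labels list them. Array medians lay between 5.33 and 5.50 on the log2 scale, and the spread of values within an array (interquartile range) was 2.91 ± 0.13 (SD, n = 21) in controls, 2.86 ± 0.12 (n = 26) in patients without recurrence and 2.82 ± 0.10 (n = 5) in patients with recurrence. That spread differed between patients and controls by -0.05 log2 (permutation test, two-sided, p = 0.156). The first principal component carried 36.2% of the variance and followed the interquartile range of the arrays closely (Pearson's r = 0.973 and Spearman's rho = 0.966 in absolute size, permutation p = 1e-05 for each, the smallest the permutations can give). Without the 2 arrays farthest from the median, r was 0.97. The number of arrays limits the precision of every value below.

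The first comparison, of patients with controls, addressed which transcripts of circulating cells differ after an infarction. In patients, transcripts of natural killer (NK) and cytotoxic lymphocytes were lower. KLRF1, which encodes an activating NK cell receptor, fell by 0.82 (SE 0.16) on the log2 scale, from 10.27 ± 0.57 (SD, n = 21) in controls to 9.45 ± 0.61 (n = 31) in patients. Transcripts with higher values included CR1, the complement receptor of blood cells, which rose by 0.69 (SE 0.17), from 9.12 ± 0.58 to 9.81 ± 0.64. CR1 stayed called in 39 of the 52 fits that leave out 1 array. Of the 14319 genes tested with limma, 69 passed an adjusted p of 0.05, 17 of them higher and 52 lower in patients, and the changes were small, between 0.16 and 0.82 log2 in size. At an unadjusted p under 0.05, 2258 genes passed, where 716 would on average by chance. Genes move together on the arrays, so such a count can lie far from 716 by chance alone.

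Among the 10 largest falls, 4 belonged to the list of cytotoxic and NK cell genes. Besides KLRF1 (adjusted p = 0.00965, limma), these were KLRB1, the lectin-like receptor CD161 (-0.77, SE 0.14, adjusted p = 0.00742), GZMB, the cytotoxic granule protease granzyme B (-0.72, SE 0.15, adjusted p = 0.0114), and KLRD1, the receptor subunit CD94 (-0.68, SE 0.15, adjusted p = 0.023), which was read by a possibly cross-hybridising probe set. These transcripts were below the control mean in 29, 28, 28 and 27 of 31 patients, in that order. Such counts, here and for the rises below, are no separate support, because the genes were chosen by their change in this same comparison. TRDV3, a variable segment of the gamma-delta T cell receptor, fell by 0.75 (SE 0.18), and PTGDR, a prostaglandin D2 receptor, fell by 0.74 (SE 0.17). AKR1C3, an aldo-keto reductase, fell by 0.74 (SE 0.17), and MYBL1, a transcription factor of the MYB family, fell by 0.65 (SE 0.16), although the other probe sets of MYBL1, at 6.84 and 5.04 in patients, gave differences of -0.0025 and -0.014. P2RY12, the ADP receptor of platelets, fell by 0.76 (SE 0.18), with its other probe set at -0.63 (SE 0.14). MMD, named for monocyte to macrophage differentiation, fell by 0.62 (SE 0.15), with its other probe set at -0.56 (SE 0.12). The adjusted p of these genes lay between 0.027 for AKR1C3 and 0.0426 for MYBL1. Of the 52 fits that leave out 1 array, KLRF1, KLRB1, GZMB and KLRD1 were called in all, AKR1C3 in 50, PTGDR in 46, TRDV3 in 37, P2RY12 in 35, MMD in 26 and MYBL1 in 20.

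Among the 10 largest rises, CR1 was above the control mean in 27 of 31 patients (adjusted p = 0.0369, limma) and each of its 5 probe sets was higher in patients. FOLR1, a folate receptor, rose by 0.64 (SE 0.12, adjusted p = 0.00742) and was above the control mean in 29 patients. That value came from 1 probe set, while the other, at 4.25 in patients and 4.24 in controls, lay below the filter on dim probe sets and gave a difference of 0.01 (SE 0.06). TMEFF2, a transmembrane protein, rose by 0.58 (SE 0.13, adjusted p = 0.027), again by 1 probe set, while its other probe sets lay at 3.32 and 3.02 in patients and gave differences of 0.00063 and 0.015. LOC400499, an uncharacterised locus, rose by 0.52 (SE 0.10, adjusted p = 0.00742) and was above the control mean in 30 patients. ASGR2, a subunit of the asialoglycoprotein receptor, rose by 0.52 (SE 0.13), SHKBP1 by 0.41 (SE 0.09), and FES, a tyrosine kinase, by 0.34 (SE 0.08). CNN2, the actin-binding calponin 2, rose by 0.32 (SE 0.06), read by a possibly cross-hybridising probe set, and UBA1, the ubiquitin-activating enzyme, by 0.27 (SE 0.06), with a second probe set at -0.01 (SE 0.06). TNIP1, an inhibitor of NF-kB signalling, rose by 0.28 (SE 0.07) at the probe set used, while its second probe set gave -0.08 (SE 0.09). Of the 52 fits that leave out 1 array, FOLR1, LOC400499, CNN2 and UBA1 were called in all, SHKBP1 in 51, TMEFF2 in 50, CR1 in 39, ASGR2 and FES in 24 each and TNIP1 in 19.

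**Figure D1:**
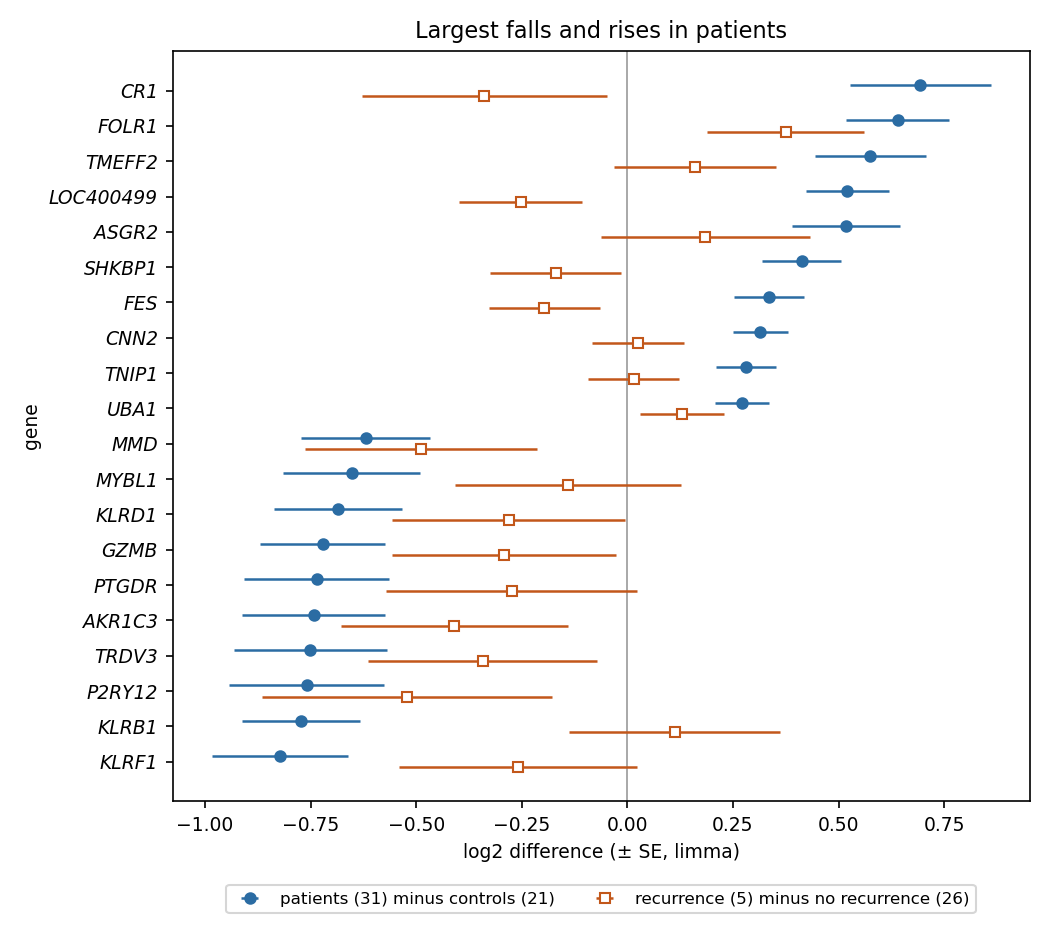
Log2 difference (horizontal axis, ± SE) of the 10 largest rises and 10 largest falls among the genes called in patients against controls. Filled circles give 31 patients minus 21 controls, where KLRF1 lies at -0.82 and CR1 at 0.69, and open squares give 5 patients with recurrence minus 26 without, where none of the genes was called.

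Of the 31 gene lists fixed before the data were examined, 11 were called with limma's camera at a preset correlation of 0.01. The cytotoxic and NK cell list was called with camera, with fry and with a permutation test of its mean, and not with camera at an estimated correlation. Its median change was -0.58, 16 of its 17 tested members were lower, and 5 of them were called over all genes, 12 when adjusted over the list alone. The fifth called member, named after its value was seen, was PRF1, the pore-forming protein perforin (-0.59, SE 0.13, adjusted p = 0.027). The mean of the list per array was 8.77 ± 0.44 (SD, n = 31) in patients and 9.23 ± 0.41 (n = 21) in controls, and 26 of 31 patients lay below the control mean (permutation test, two-sided, p = 0.00046, adjusted over 31 lists p = 0.0143). The adjusted p was 4.95e-13 with camera at the preset correlation, 0.00722 with fry, and 0.228 with an estimated correlation.

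The other lists were called at the preset correlation only. All 18 tested mature neutrophil genes were above 0, with a median of 0.31, but none was called over all genes and 7 were when adjusted over the list alone. The adjusted p of this list was 4.38e-07 with camera, 0.647 with an estimated correlation, and 0.157 for the permutation test of its mean. Its leading members were the calgranulins S100A12 (0.80, SE 0.22, adjusted p = 0.0667), S100A8 (0.23, SE 0.07) and S100A9 (0.48, SE 0.15), and the membrane protease MMP25 (0.47, SE 0.15). Of the 16 platelet and megakaryocyte genes, 15 were below 0, with a median of -0.24, and none was called (2 when adjusted over the list alone). They were led by the platelet tubulin TUBB1 (-0.54, SE 0.15) and the platelet chemokine PPBP (-0.34, SE 0.12), followed by SPARC (-0.41, SE 0.17) and PF4V1 (-0.62, SE 0.26), and the list's adjusted p was 0.729 with an estimated correlation. Platelets carry no nucleus, and the RNA came from the nucleated cell fraction of the blood. Of 20 genes of IL-1, IL-18 and Toll-like receptor signalling, 18 were above 0, with a median of 0.19, none called and 2 adjusted over the list alone. They were led by the flagellin receptor TLR5 (0.54, SE 0.15), the receptor antagonist IL1RN (0.43, SE 0.14), NLRC4 (0.39, SE 0.15) and IL1R1 (0.50, SE 0.19), and the adjusted p was again 0.729 with an estimated correlation. With the neutrophil, T cell and erythroid means as covariates, the median of this list turned to -0.01.

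Further lists with higher values in patients were hypoxia and glycolysis (median 0.10 over 18 genes, none called and 2 adjusted over the list alone), complement (0.13 over 13 genes, 1 called, CR1) and classical monocyte (0.14 over 14 genes, none called). Their adjusted p with an estimated correlation was 0.647 for hypoxia and glycolysis and for complement, and 0.729 for classical monocyte. Among them, the vasodilator peptide ADM had a difference of 0.70 (SE 0.21, adjusted p = 0.0986) and the monocyte receptor CD14 one of 0.33 (SE 0.15, adjusted p = 0.258). Lists with lower values were TGF-beta and Wnt signalling (median -0.09 over 20 genes), T cell (-0.15 over 16 genes), cytosolic ribosomal protein (-0.08 over 17 genes) and oxidative phosphorylation (-0.08 over 18 genes). Their adjusted p with an estimated correlation was 0.647, 0.770, 0.755 and 0.831, in that order. In the first of these, SMAD7, an inhibitor of TGF-beta signalling, was the 1 called gene (-0.55, SE 0.12, adjusted p = 0.013, called in all 52 fits that leave out 1 array). Across arrays within groups, SMAD7 followed the mean of the cytotoxic and NK cell list (r = 0.775). Its fall therefore cannot be told apart from that of the cytotoxic genes. In the T cell list the called gene was CD247, the zeta chain of the T cell receptor complex (-0.41, SE 0.10, adjusted p = 0.0382, called in 31 of the 52 fits). RPS24 led the ribosomal list (-0.15, SE 0.06, adjusted p = 0.174), and none of the members of that list or of the oxidative phosphorylation genes was called. Among the alternative settings, the RPS24 difference lay between -0.73 and -0.096. Leaving out 1 array moved the T cell median to -0.06 and ended its call at the preset correlation (without no-recurrence replicate 4). The ribosomal median moved to -0.13 without control replicate 21. The classical monocyte list was called in 47 of 52 fits (not without no-recurrence replicates 2 and 14 or control replicates 3, 7 and 17) and oxidative phosphorylation in 31 of 52. With the array interquartile range as a covariate, the oxidative phosphorylation median turned to 0.02.

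The number of called genes depended on single arrays, ranging from 27 without control replicate 8 to 369 without control replicate 21. Repeated quantile normalization called 306 genes, 134 higher and 172 lower, against 17 higher and 52 lower in the values as deposited. The balance turned with the array interquartile range as a covariate (109 higher and 82 lower) and without the 5 arrays least alike to the others (260 and 186).

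**Figure D2:**
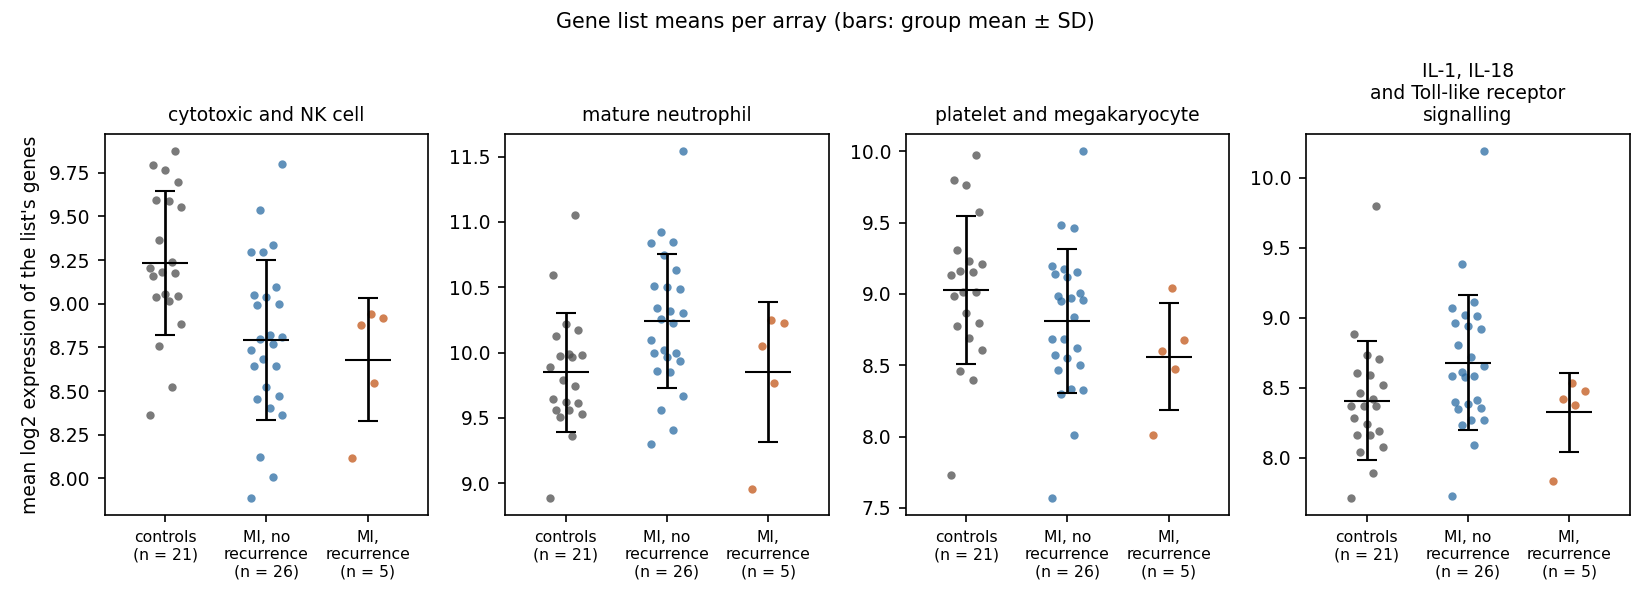
Mean log2 expression (vertical axis) of the tested genes of 4 lists on each array, by group, with points for single arrays and bars for the group mean ± SD. The cytotoxic and NK cell means were 9.23 in 21 controls, 8.79 in 26 patients without recurrence and 8.68 in 5 patients with recurrence, and the mature neutrophil means were 9.85, 10.24 and 9.85 in the same order.

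The second comparison set patients with a later recurrent event against those without one, to ask which transcripts differ with long-term outcome. No gene separated the groups after adjustment. Mature neutrophil genes and genes of IL-1, IL-18 and Toll-like receptor signalling had lower values with recurrence. Their medians were -0.37 over 18 genes (-0.19 without recurrence replicate 3) and -0.35 over 20 genes (-0.0099 at the smallest among the alternative settings). Neither list separated the groups in a test that takes the correlation of its genes from the data (adjusted p = 0.534 for each with an estimated correlation). Of 14319 genes tested with limma, 0 passed an adjusted p of 0.05 and 588 had an unadjusted p under 0.05. By chance 716 would on average, and other splits of the same arrays gave a median of 393. Single arrays moved the count of 588, to 491 without recurrence replicate 4 and to 828 without no-recurrence replicate 7. The lowest adjusted p was 0.958. The median 95% confidence interval of a gene was ± 0.26 log2, against ± 0.15 for patients and controls.

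The 5 genes with higher values and the smallest unadjusted p were EIF5A, a translation factor (0.30, SE 0.08, possibly cross-hybridising), LINC02175 (0.27, SE 0.08), PARD6G-AS1 (0.25, SE 0.07), NOC2L (0.30, SE 0.09) and RBP4, the retinol-binding protein (0.32, SE 0.10). A second probe set of NOC2L gave a difference of -0.04. The 5 with lower values were SIRPB2, a signal-regulatory protein (-0.69, SE 0.19), FAR2, a fatty acyl-CoA reductase (-0.83, SE 0.23), DAPP1, an adaptor protein (-0.44, SE 0.12), DNA2, a nuclease and helicase (-0.38, SE 0.11), and ANKRD33B (-0.35, SE 0.10). In each of these genes but ANKRD33B (4 of 5), all 5 arrays with recurrence lay on the same side of the mean of the 26 without. That is no separate support, because the genes were chosen by their p in this same comparison. None of these genes differed from chance after adjustment (adjusted p = 0.958 for each, limma).

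Camera at the preset correlation called 11 lists, 8 lower and 3 higher with recurrence, and none of them was called with an estimated correlation. The adjusted p with an estimated correlation was 0.333 for apoptosis, 0.534 for the mature neutrophil, IL-1, IL-18 and Toll-like receptor, NF-kB and TNF response, and coagulation lists, and 0.703 for the other 6 of them. In the mature neutrophil list 17 of 18 members were below 0, led by VNN3P (-0.60, SE 0.24), MMP25 (-0.50, SE 0.24), the glucosidase MGAM (-0.75, SE 0.37) and the chemokine receptor CXCR2 (-0.58, SE 0.31). Among the alternative settings, the MMP25 difference shrank as far as -0.0071. All 20 members of the IL-1, IL-18 and Toll-like receptor list were below 0, led by IL1B (-0.70, SE 0.34), the endotoxin receptor TLR4 (-0.56, SE 0.29, possibly cross-hybridising), TLR1 (-0.44, SE 0.26) and IL18RAP (-0.53, SE 0.32). The apoptosis list had a median of -0.23 over 16 genes, with BID at -0.38 (SE 0.14) and MCL1 at -0.32 (SE 0.16). The platelet and megakaryocyte list had a median of -0.29 over 16 genes, with TUBB1 at -0.54 (SE 0.24) and GP1BA at -0.34 (SE 0.21). Leukocyte adhesion and migration (-0.16 over 14 genes), NF-kB and TNF response (-0.19 over 13 genes), coagulation and fibrinolysis (-0.25 over 11 genes) and immediate early genes (-0.23 over 16 genes) made up the rest of the lower lists, with PTGS2, the inducible cyclooxygenase, at -0.89 (SE 0.42), FPR1 at -0.45 (SE 0.27), THBD at -0.50 (SE 0.32) and FOS at -0.58 (SE 0.35). The higher lists were erythroid and reticulocyte (0.51 over 12 genes, all above 0), led by SLC4A1, the anion exchanger of red cells (0.62, SE 0.45), T cell (0.19 over 16 genes, all above 0), with CD3E at 0.36 (SE 0.14), and cytosolic ribosomal protein (0.11 over 17 genes, all above 0), with RPL35A at 0.22 (SE 0.12, possibly cross-hybridising). No member of any list was called, over all genes or adjusted over the list alone. Several medians moved by over 1.5 times on leaving out 1 array with recurrence. The erythroid list lay at 0.32, 0.28, 1.11 and 0.31 without replicates 1, 2, 3 and 5, in that order. It was called in 24 of 31 fits (not without recurrence replicates 1, 2, 4 and 5 or no-recurrence replicates 2, 6 and 9). SLC4A1 lay at 1.32 without recurrence replicate 3 and at 0.30 without replicate 5. Without recurrence replicate 3, the mature neutrophil (-0.19), T cell (0.06), ribosomal (0.04), coagulation (-0.05), NF-kB and TNF response (-0.18) and immediate early (-0.18) lists were not called, and the apoptosis list lay at -0.14. Of the genes named here, MGAM then lay at -0.39, CXCR2 at -0.35, IL1B at -0.41, TLR4 at -0.29, TLR1 at -0.21, PTGS2 at -0.44, FPR1 at -0.28, THBD at -0.14, FOS at -0.36 and RPL35A at 0.13. The T cell and ribosomal lists lay at 0.37 and 0.21 without replicate 5. Without replicate 4 the platelet list was not called (-0.15) and GP1BA lay at -0.16. Without replicate 2 the NF-kB list lay at -0.09 and the immediate early list was not called (-0.11). Without the 5 arrays least alike to the others, the T cell and ribosomal medians both turned to -0.02 and neither list was called (adjusted p = 0.725 for each, camera). The mature neutrophil list (-0.18, adjusted p = 0.242, camera) was not called in that setting either. Nor were the platelet, apoptosis, NF-kB and TNF response, immediate early and coagulation lists. The IL-1, IL-18 and Toll-like receptor (-0.22), adhesion and migration (-0.22) and erythroid (1.14) lists stayed called. With the neutrophil, T cell and erythroid means as covariates, the adhesion and migration median turned to 0.02. Across 16 alternative settings, the median of the IL-1, IL-18 and Toll-like receptor list lay between -0.38 and -0.0099. That list was not called in 4 of them.

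Nor was any of the 11 lists called with fry or with an exact permutation test of the list mean per array over all 169911 splits of the 31 patients. In the exact permutation test, two-sided, the apoptosis list had the smallest p (8.96 ± 0.15 against 9.17 ± 0.18, SD, p = 0.0258, adjusted p = 0.799), and the mature neutrophil list had an adjusted p of 0.819 (9.85 ± 0.53 against 10.24 ± 0.51). Leaving out 1 array at a time moved the number of lists called by camera between 5, without recurrence replicate 3, and 16, without recurrence replicate 5.

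**Figure D3:**
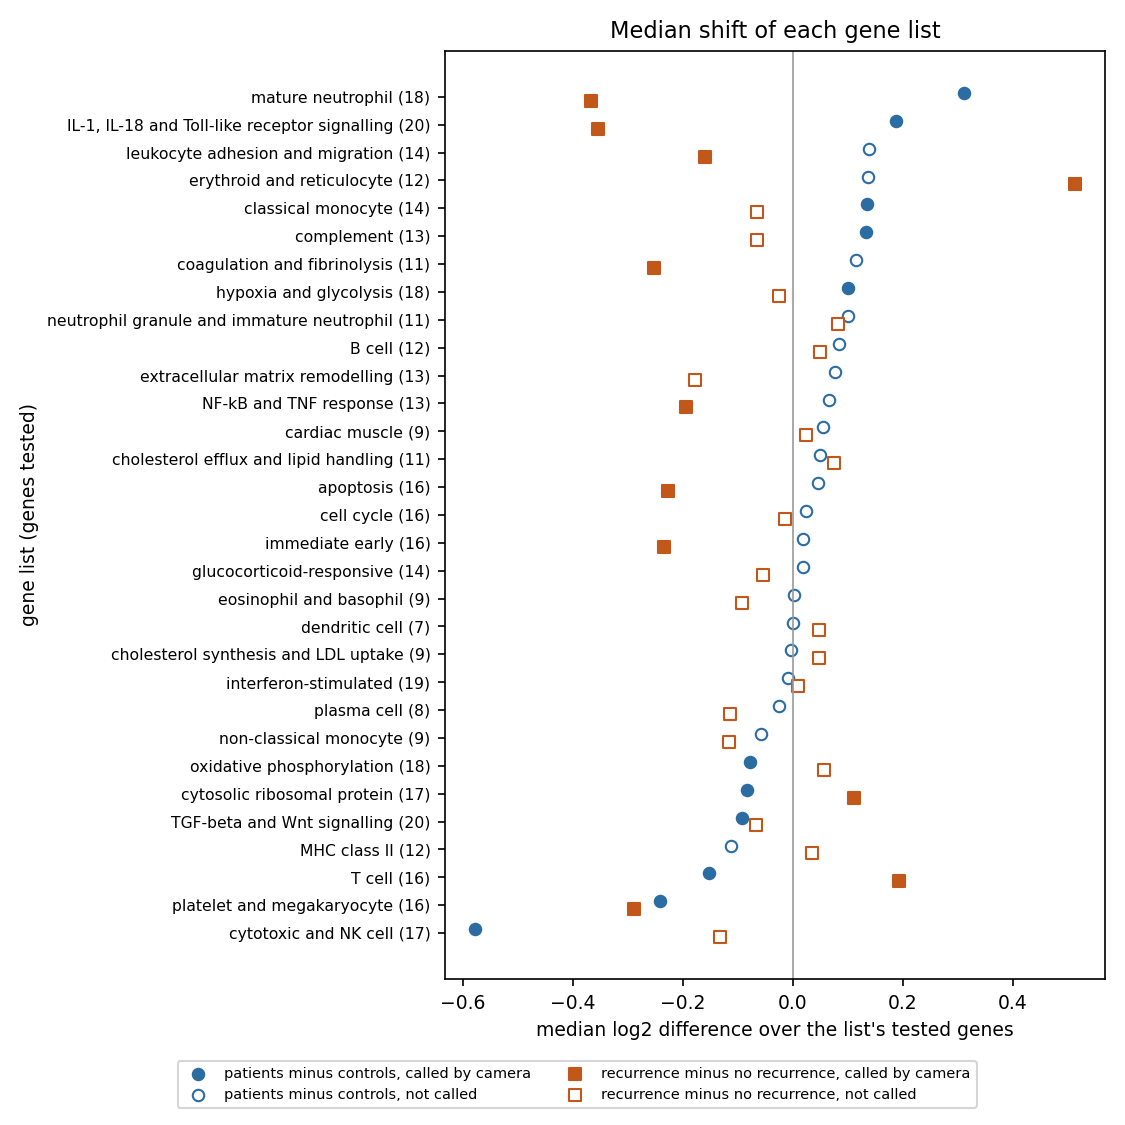
Median log2 difference (horizontal axis) over the tested genes of each of the 31 lists, circles for patients minus controls and squares for recurrence minus no recurrence, filled where camera at the preset correlation called the list. The mature neutrophil list lay at 0.31 in the first and at -0.37 in the second comparison, and the cytotoxic and NK cell list at -0.58 and -0.13.

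Each patient group was then set against the 21 controls in a fit of all 3 groups with limma. In patients without recurrence, cytotoxic transcripts were lower and CR1 was higher, as in all patients together. KLRB1 fell by 0.79 (SE 0.15, adjusted p = 0.00623), KLRF1 by 0.78 (SE 0.17, adjusted p = 0.031) and GZMB by 0.67 (SE 0.15, adjusted p = 0.0427). LOC400499 rose by 0.56 (SE 0.10, adjusted p = 0.00589), CR1 by 0.75 (SE 0.17, adjusted p = 0.0434), FOLR1 by 0.58 (SE 0.12, adjusted p = 0.031), and SHKBP1, FES and CNN2 by 0.44, 0.37 and 0.31. In all, 25 genes were called, 8 higher and 17 lower, and 1874 had an unadjusted p under 0.05. The cytotoxic and NK cell list had a median of -0.56 (adjusted p = 1.02e-12 with camera, 0.258 with an estimated correlation and 0.0188 with fry), and the mature neutrophil list one of 0.35 (adjusted p = 6.59e-11 with camera and 0.463 with an estimated correlation). Leaving out 1 array at a time gave between 5 genes and, without control replicate 21, 165 genes. More genes were called higher than lower after repeated quantile normalization (64 and 60), with array weights (151 and 114), with the array interquartile range as a covariate (66 and 46) and without the 5 arrays least alike to the others (209 and 62). The balance of rises and falls thus depended on the setting.

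In the 5 patients with recurrence, 0 genes were called against controls with limma, and 1695 had an unadjusted p under 0.05. The differences of 15 of the 20 genes with the largest rises and falls were larger in size than in the other patients. These were P2RY12 (-1.20, SE 0.32), AKR1C3 (-1.09, SE 0.29), KLRF1 (-1.04, SE 0.28), TRDV3 (-1.04, SE 0.32), MMD (-1.03, SE 0.26), GZMB (-0.97 against -0.67), PTGDR (-0.96 against -0.69), KLRD1 (-0.92 against -0.64), MYBL1 (-0.77 against -0.63), FOLR1 (0.95, SE 0.21), TMEFF2 (0.71 against 0.55), ASGR2 (0.67 against 0.49), UBA1 (0.38 against 0.25), CNN2 (0.34 against 0.31) and TNIP1 (0.29 against 0.28). The other 5 were smaller, CR1 (0.41, SE 0.29, against 0.75), LOC400499 (0.31 against 0.56), SHKBP1 (0.27 against 0.44), FES (0.17 against 0.37) and KLRB1 (-0.68 against -0.79). In the direct test of that difference none of the 20 genes passed (adjusted p = 0.958 or more, limma). The cytotoxic and NK cell list had a median of -0.68 (adjusted p = 5.2e-08 with camera and 0.568 with an estimated correlation), and the platelet and megakaryocyte list one of -0.50 (adjusted p = 3e-05 with camera and 0.982 with an estimated correlation). The mean of the cytotoxic list did not separate the patient groups (8.68 ± 0.35 with and 8.79 ± 0.46 without recurrence, SD, exact permutation test, two-sided, p = 0.611). Apoptosis (median -0.20, adjusted p = 0.0039 with camera and 0.568 with an estimated correlation) and TGF-beta and Wnt signalling (-0.09, adjusted p = 0.045 with camera and 0.982 with an estimated correlation) were the other lists called. The mature neutrophil list, higher in all patients together, had a median of -0.0020 here, with 9 of 18 genes above 0. The IL-1, IL-18 and Toll-like receptor list had one of -0.11, with 7 of 20 genes above 0. Neither was called (adjusted p = 0.834 and 0.455, camera).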

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

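The comparison of the cytotoxic list with the T cell and B cell lists and the fit with FOLR3 as a covariate were chosen after the results were seen. The 69 genes called in patients against controls exceeded chance, since only 1 of 100 splits of the 52 arrays, the real one, gave as many and the highest of the others called 1 gene. For patients without recurrence against controls, 3 of 100 splits gave at least the real 25 genes. The highest of the others called 3485, which points to a structure among the arrays other than the groups. For recurrence against no recurrence chance could not be excluded, with 34 of 100 splits giving at least the 588 genes at an unadjusted p under 0.05, up to 4025 genes, and 8 other splits calling genes after adjustment, up to 334. For patients with recurrence against controls it could not be excluded either (6 of 100 splits gave at least 1695 genes at an unadjusted p under 0.05, up to 3118). The counts of lists called by camera at the preset correlation did not exceed chance in either comparison. For patients against controls 35 of 100 splits gave at least 11 lists, up to 22, and for recurrence 35 of 100 gave at least 11, up to 20, so these calls describe lists whose genes move together on the arrays and are weak evidence for a difference between the groups.

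The first pattern is the lower level of cytotoxic and NK cell genes in patients. The difference of the list mean was -0.459 (95% interval -0.702 to -0.216). It remained -0.429 (-0.676 to -0.182) with the array interquartile range in the model, so that range does not account for it. The range itself differed little between patients and controls (-0.05 log2), so this fit cannot decide on array quality at large. A dilution of all lymphocytes by other cells is argued against, since the list mean minus the mean of the T cell and B cell lists was lower in patients by -0.43 (-0.763 to -0.096). Against the T cell list alone, however, the difference was -0.31 (-0.624 to 0.00245). Fewer cytotoxic cells in the blood of patients is a candidate explanation. Of the 47 fallen genes outside the list, 36.2% followed its mean across arrays within groups. Among the 14238 genes that were neither called nor in the list, 1.07% did. With that mean as a covariate none of the 47 stayed called. Their median difference went from -0.44 (median SE 0.10) to -0.25 (median SE 0.09), so that the calls ended mainly because the difference shrank. The covariate was itself lower in patients, so it can shrink falls in patients whatever their cause. Genes that did not follow the list lost their calls too. The loss of calls therefore cannot tell fewer cytotoxic cells from other causes. A lower expression per cell, or a loss of these cells in sampling or fractionation that differed between groups, stays open, because neither was measured. No batch or donor trait was in the model, and nearly all patients come before the controls in the order of the samples. A difference in processing or in donor traits therefore cannot be told apart from the infarction.

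The second pattern is the lower level of mature neutrophil and IL-1, IL-18 and Toll-like receptor genes with recurrence, by -0.37 (SE 0.23) in the mean of both lists. A chance difference between 5 and 26 arrays may account for it (exact permutation test, two-sided, p = 0.124). The difference was -0.345 (95% interval -0.828 to 0.138) with the array interquartile range in the model, and the smallest value on leaving out 1 array with recurrence was -0.197, so array quality and the pull of 1 array cannot be told apart from a difference in blood cells with 5 arrays. A lower neutrophil share in these patients stays open as untested.

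The third pattern is the FOLR1 probe set, higher in patients by 0.64 (SE 0.12), in cells where its second probe set lay at 4.25. Transcripts of the paralog FOLR3, a neutrophil gene, could reach the probe set, and FOLR3 itself had a difference of 0.68 (SE 0.27, adjusted p = 0.236, limma over probe sets). The FOLR1 probe set did not follow that of FOLR3 across 52 arrays within groups (Pearson's r = -0.0401, permutation p = 0.775, adjusted over 2 relations p = 0.775, Spearman's rho = -0.0205, permutation p = 0.885, and r = -0.09 without the 2 arrays farthest from the median), but r went both ways by group, at 0.236 in controls, 0.247 with recurrence and -0.243 without recurrence. With FOLR3 as a covariate, with a slope of its own in patients and in controls, the FOLR1 difference was 0.612 (95% interval 0.34 to 0.883). A covariate with so weak a relation within groups can hardly shrink the difference, so this fit adds no separate evidence. The weak relation itself argues against a rise of FOLR3 as the whole source. A part from FOLR3, and which transcript the probe set reads, stay open.

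In the 5 arrays with recurrence, 144 items were examined, namely named genes, list means and array measures such as the median and interquartile range. By Dixon's criterion 13 of them had 1 array far from the others, where chance alone gives about 7.2, since it marks about 1 in 20. Genes and the lists that hold them are not independent, so the 13 against 7.2 was not tested and shows no excess by itself. The gap to the nearest array, as a share of the range (critical value 0.71), was 0.73 for TNIP1, 0.782 for C2, 0.726 for NOC2L, 0.723 for CXCR2, 0.721 for CCR1 and 0.855 for TLR4. Among erythroid genes it was 0.765 for SLC4A1, 0.738 for BPGM and 0.886 for FECH. Among list means it was 0.831 for erythroid and reticulocyte, 0.773 for IL-1, IL-18 and Toll-like receptor signalling, 0.769 for glucocorticoid-responsive, and 0.868 for leukocyte adhesion and migration. In that list mean 1 array thus set most of the range of the group.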

How the results depend on the processing

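The settings with the array interquartile range, without the 5 least alike arrays, with cytotoxic and platelet means, and with permuted list means were chosen after seeing the data. For patients against controls (69 genes), each probe set by itself gave 163 calls, no _x_at or _s_at probe sets 105, quantile normalization 306, array weights 577, neutrophil, T cell and erythroid covariates 441, an unadjusted p with 1.2-fold 641, the interquartile range 191 (109 higher, 82 lower), without the 5 least alike arrays 446 (260 higher, 186 lower), and cytotoxic and platelet covariates 0. All 69 genes stayed called with array weights, with the interquartile range and without the 5 arrays. Fewer of the 69 did with median centring (46), the mean of probe sets (49), no filter (55) and the trended and robust prior (61). With cytotoxic and platelet covariates, 0 of the 64 that were tested stayed called. For patients without recurrence against controls (25 genes, 8 higher and 17 lower), no filter gave 15, the mean of probe sets 40, each probe set 39, quantile normalization 124 (64 higher, 60 lower), median centring 15, array weights 265 (151 higher, 114 lower), cell covariates 63, unadjusted p with 1.2-fold 619, the interquartile range 112 (66 higher, 46 lower), without 5 arrays 271 (209 higher, 62 lower), and cytotoxic and platelet covariates 0. For patients with recurrence against controls (0 genes), the mean of probe sets gave 1 (ZBTB44, -0.39), each probe set 1 (RABGAP1L, -0.85), both named after their values were seen, quantile normalization 12, array weights 386, cell covariates 194, unadjusted p with 1.2-fold 1077, the interquartile range 55, and without 5 arrays 16. For recurrence against no recurrence (0 genes), unadjusted p with 1.2-fold gave 361 and without 5 arrays 1 (TATDN3, -0.55, named after its value was seen). Lists called for patients against controls (11) became 5 with cell covariates (the neutrophil and T cell lists, among the 11, are covariates there and were not tested), 0 with an estimated correlation, 1 with fry and 1 with permuted means. For recurrence (11) they became 6 with array weights, 5 with cell covariates (the neutrophil, T cell and erythroid lists not tested), 0 with an estimated correlation, 0 with fry, 3 without 5 arrays, 7 with cytotoxic and platelet covariates (the platelet list not tested) and 0 with permuted means. The direction turned without _x_at and _s_at probe sets for TNIP1 (-0.0776) and for NOC2L with recurrence (-0.0364), since another probe set then stands for the gene. With cell covariates it turned for the IL-1 and Toll-like receptor list in patients (-0.0141), and for the adhesion list (0.0188) and ICAM3 (0.0386) with recurrence. With the interquartile range it turned for oxidative phosphorylation in patients (0.0163). Without 5 arrays it turned, with recurrence, for the T cell list (-0.0187), the ribosomal list (-0.0227), MAL (-0.0191), RPL34 (-0.00847) and RPL3 (-0.027). Apart from the change of probe set and of threshold, the cause was not tested.

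Leaving out 1 array at a time gave 27 to 369 genes for patients against controls, 5 to 165 for patients without recurrence against controls, 0 to 0 for both comparisons of the patients with recurrence, 9 to 14 lists for patients against controls and 5 to 16 for recurrence. For patients against controls the count moved by over 1.5 times without 15 of the arrays. It rose without control replicates 21 (369) and 3 (184) and without replicates 6 (173) and 19 (124) of the patients without recurrence. It dropped without control replicates 1 (37), 2 (40), 4 (34), 6 (28), 8 (27), 10 (30), 11 (35) and 14 (38), replicates 3 (39) and 14 (42) without recurrence and replicate 4 with recurrence (39). For patients without recurrence it moved without 25 arrays, most without control replicate 21. No paired analysis was possible because the replicate numbers only name the samples in their order. Array values near the lower end of the scale limit what can be seen of dim transcripts.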

Other observations

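The other called genes in this part were named after their values were seen, and the counts of genes that follow a list and the fit without 5 arrays were chosen after the results were seen. Called falls in patients outside the fixed cytotoxic and NK cell list, picked by hand and not tested as a group, were those of TBX21, the transcription factor T-bet (-0.55, adjusted p = 0.0301, limma), FASLG, the ligand of the death receptor FAS (-0.52, adjusted p = 0.0109), IL2RB, a subunit of the IL-2 and IL-15 receptors (-0.50, adjusted p = 0.0125), and STAT4 (-0.37, adjusted p = 0.0419). STAT4 followed the T cell list best (r = 0.805, against 0.6 for the cytotoxic list). Of the 52 fallen genes, 19 followed the mean of the cytotoxic and NK cell list best of 8 cell lists (36.5%, against 0.915% of all 14319 genes), 14 of them outside the list, and 3 the platelet list (5.77% against 1.54%), while the 7 that followed the T cell list were a smaller share than among all genes (13.5% against 24.1%). The 3 that followed platelets were P2RY12, MMD and RAB27B, the last a regulator of granule release (-0.52, adjusted p = 0.0352). Of the 17 risen genes, 4 followed mature neutrophils best (CR1, CNN2, ZYX and UBALD2, 23.5% against 6.12% of all genes), 3 classical monocytes (ASGR2, FES and UBA1, 17.6% against 8.88%) and none the cytotoxic list, while the 2 that followed the erythroid list (TNIP1 and TMEFF2) were a smaller share than among all genes (11.8% against 19.8%). The shares of the risen genes were not tested. Classical monocytes were also followed best by 2 fallen genes, HIPK2 and ADCY7 (3.85% of the fallen genes).

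Without the 5 arrays least alike to the others (1 control, 3 patients without and 1 with recurrence), a choice made after seeing the data, the 10 largest called rises in patients were ANXA3 (1.07, SE 0.20), ARG1 (0.99, SE 0.24), S100A12 (0.97, SE 0.18), MCEMP1 (0.85, SE 0.17), MMP9 (0.82, SE 0.23), SOCS3 (0.82, SE 0.19), CR1 (0.81, SE 0.13), ADM (0.80, SE 0.21), DSC2 (0.79, SE 0.18) and TDRD9 (0.75, SE 0.18), with adjusted p between 0.000379 and 0.0357, and of these CR1 alone was called over all arrays. In that fit 7 of 18 mature neutrophil genes, 7 of 20 genes of IL-1, IL-18 and Toll-like receptor signalling and 6 of 18 hypoxia and glycolysis genes were called higher, and 8 of 17 cytotoxic genes lower. None of these 4 lists was called with an estimated correlation (adjusted p = 0.157, 0.260, 0.127 and 0.127, in that order), and the adjusted p with fry was 0.00487, 0.0160, 0.00298 and 0.00376.

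The lists not called in patients against controls had these medians: extracellular matrix remodelling 0.08, neutrophil granule and immature neutrophil 0.10, non-classical monocyte -0.06, cardiac muscle 0.05, B cell 0.08, cholesterol efflux and lipid handling 0.05, MHC class II -0.11, leukocyte adhesion and migration 0.14, cholesterol synthesis and LDL uptake -0.0027, erythroid and reticulocyte 0.14, coagulation and fibrinolysis 0.12, NF-kB and TNF response 0.07, apoptosis 0.05, dendritic cell 0.00013, glucocorticoid-responsive 0.02, immediate early 0.02, interferon-stimulated -0.01, eosinophil and basophil 0.0019, plasma cell -0.03 and cell cycle 0.02. The apoptosis, eosinophil and basophil, and cell cycle lists had a mean of the opposite sign (-0.04, -0.02 and -0.02). In recurrence against no recurrence the lists not called had medians of -0.18 for extracellular matrix remodelling, -0.06 for complement, -0.13 for cytotoxic and NK cell, -0.05 for glucocorticoid-responsive, -0.12 for non-classical monocyte, -0.06 for classical monocyte, -0.07 for TGF-beta and Wnt signalling, -0.09 for eosinophil and basophil, -0.11 for plasma cell, -0.03 for hypoxia and glycolysis, -0.01 for cell cycle, 0.06 for oxidative phosphorylation, 0.01 for interferon-stimulated, 0.08 for neutrophil granule and immature neutrophil, 0.07 for cholesterol efflux and lipid handling, 0.02 for cardiac muscle, 0.05 for B cell, 0.04 for MHC class II, 0.05 for cholesterol synthesis and LDL uptake and 0.05 for dendritic cell. The interferon-stimulated and the cholesterol efflux lists had a mean of the opposite sign (-0.03 and -0.08).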
